A study of Mus musculus with 4 samples.

How the data were processed

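The series holds 4 small RNA libraries from mouse retina at E18.5, 2 of Ptf1a+/- and 2 of Ptf1a-/- embryos. Genotype and replicate number were taken from the sample titles and characteristics. Per the labels' protocols, total RNA was extracted with TRIzol, RNA of 18 to 30 nt was cut from a denaturing gel starting from 1 µg of total RNA, libraries were made with a New England Biolabs small RNA kit, and cDNA of 60 to 80 nt was cut from a second gel. Both size cuts, adapter ligation and PCR favour some sequences over others, so levels of different miRNAs are less comparable than levels of 1 miRNA between libraries. No molecular identifiers are described, so reads of 1 PCR product count more than once, and intervals and limits cover counting error only. Reads were demultiplexed with bcl2fastq 2.20.0.422, per the submitters' processing notes. The aligner, counter and genome build are not given in the sources used here.

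3 deposited tables were used, each with a column per library, and no column was left without a sample. The authors' table of raw values per mature miRNA held estimated counts: 5.73 to 7.84% of values per library were not whole, and the rows concerned held 15.2 to 36.5% of a library's counts. Listed counts summed to between 3647145 and 4385834 per library. A count of 0 thus allows a level of up to 0.684 to 0.823 CPM of the listed counts (at 3 counts, without TMM scaling). The values were rounded to whole numbers before the count tests. Whole counts had been assumed when the design was fixed. The deposited CPM table held the same counts divided by 1 total per library (the ratio was constant to within 0.00204% over miRNAs), and this total exceeded the listed counts by an amount equal to 16.3 to 27.9% of it; what it counts is not given in the sources used here. The third deposited table is text and gives the most frequent sequence per miRNA and library. Per the file headers it is written against miRBase22, with lower case for a base that differs and signs for extended ends.

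The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, legacy=FALSE, robust=FALSE) of Ptf1a-/- against Ptf1a+/- on the rounded counts, with TMM scaling and genotype as the only term, over the 584 of 1326 miRNAs with 10 or more counts in at least 2 libraries. TMM factors were 1.06, 1.07 (Ptf1a+/-), 1.06 and 0.829 (Ptf1a-/-). p-values were adjusted by Benjamini-Hochberg and called under 0.05. Levels are TMM-scaled CPM, mean ± SD over 2 libraries; errors of log2 fold changes are SE derived from the fit. An exact permutation test of 2 libraries against 2 cannot give a p under 0.333, so tests that share the spread over miRNAs were used. The spread within the genotypes is unequal, and this fit pools it. In 20 simulations of the comparison with no effect and that unequal spread, miRNAs drawn independently, it called none of the 584 miRNAs, with 36.8 at an unadjusted p under 0.05 on average. The simulated libraries were independent, with a single spread per genotype for all miRNAs. The fit was thus not tried on a Ptf1a+/- pair from 1 RNA sample, and its calls may still hold false positives. With 200 of 584 miRNAs changed and the same unequal spread it recovered 24.5% of those changed 1.5-fold, 60.8% at 2-fold and 93.4% at 4-fold; with the Ptf1a+/- libraries summed into 1 these shares were 0.970, 14.3 and 77.0%.

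12 miRNA lists were fixed before the data were examined: the miR-216 and miR-217 cluster, the miR-183, miR-96 and miR-182 cluster, neuron-enriched miRNAs, retinal progenitor timing miRNAs, the miR-17/92 paralog clusters, the miR-181 family, the Dlk1-Dio3 imprinted locus, and markers of pigment epithelium, lens and surface epithelium, blood cells, vessels and mural cells, and striated muscle. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation; with the latter no list passed after adjustment, nor did any with limma's directional fry test (lowest adjusted p 0.0582). With fry's mixed test, which takes changes both ways and was added after seeing the data, the Dlk1-Dio3 and miR-17/92 lists passed (adjusted p = 0.00284 and 0.0122). The named miRNAs follow a rule that was also fixed then: all measured arms of the miR-216 and miR-217 cluster, the 10 largest changes in each direction among called miRNAs whose genotypes did not overlap, the 3 smallest p-values of each list and the 10 highest mean CPM. Other names are said to have been chosen after their values were seen.

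miRNAs were placed on GRCm38 by an exact match of their reference-like most frequent sequence to the miRNA precursors of GENCODE M21; 484 of 584 matched a single precursor, 67 several and 33 none, and positions are given for the first group only. Host genes and exons come from the same annotation. Counting intervals are exact (Clopper-Pearson, 95%) on counts summed per genotype and scaled by effective library size.

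Alternatives fixed before the data were examined were DESeq2 size factors in the edgeR fit, upper-quartile scaling, library size only, no count filter, 100 counts in 2 libraries, the earlier quasi-likelihood fit, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited CPM plus 1 or 0.5 with and without a filter, the replicate number as a block, and leaving out each library. Summing the Ptf1a+/- libraries into 1 was added after seeing the data. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The groups hold 2 libraries each, too few for a test of single outlying libraries or of other splits of the libraries.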

Results

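Small RNA was sequenced from whole retina of mouse embryos at E18.5, a late embryonic stage at which the retina holds dividing progenitors and newly formed neurons. The embryos were heterozygous for a loss of Ptf1a (Ptf1a+/-, 2 libraries) or lacked both functional copies (Ptf1a-/-, 2 libraries). Ptf1a encodes a basic helix-loop-helix transcription factor that progenitors need in order to form amacrine and horizontal cells, the interneurons of the inner and outer retina. The libraries held RNA of 18 to 30 nt, the size of mature microRNAs (miRNAs), so Ptf1a mRNA itself was not measured. The genotype labels could therefore not be checked against it. Total counts were 3647145 and 4385834 in Ptf1a+/- replicates 1 and 2, and 3658490 and 3917069 in Ptf1a-/- replicates 1 and 2. Of 1326 listed miRNAs, 1019, 1070, 1015 and 970 had a count in these libraries. A count of 0 allowed a level of up to 0.823, 0.684, 0.820 and 0.766 CPM (at 3 counts, counting error only). CPM here are counts scaled to a common library total, without the TMM scaling of the levels below. On the TMM scale, 3 counts in Ptf1a-/- replicate 2 are 0.924 CPM. The 10 most abundant miRNAs of each library took 67.0, 66.9, 67.9 and 72.1% of its counts. The labels do not say whether the libraries of a genotype came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

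The spread within the genotypes was unequal. The Ptf1a+/- libraries had a biological coefficient of variation of 1.39%, against 22.6% between the Ptf1a-/- libraries. Pairs of libraries were compared over miRNAs with 20 to 2000 counts summed over the pair. The Ptf1a+/- libraries differed by little more than sampling noise (chi-square per degree of freedom 1.11, p = 0.0520), while the Ptf1a-/- libraries differed by far more (8.68). Over all miRNAs with 20 or more summed counts the Ptf1a+/- pair differed beyond sampling noise (chi-square per degree of freedom 1.85, p = 5.30e-32). This sets the pair against read sampling only, so it cannot tell separate animals from preparations of 1 RNA sample. Both were kept as replicates, and this result is no ground for that choice. The total behind the deposited CPM exceeded the listed counts by 17.05 and 16.3% of that total in Ptf1a+/- and 22.7 and 27.9% in Ptf1a-/-, so this share moved with genotype.

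**Figure D1:**
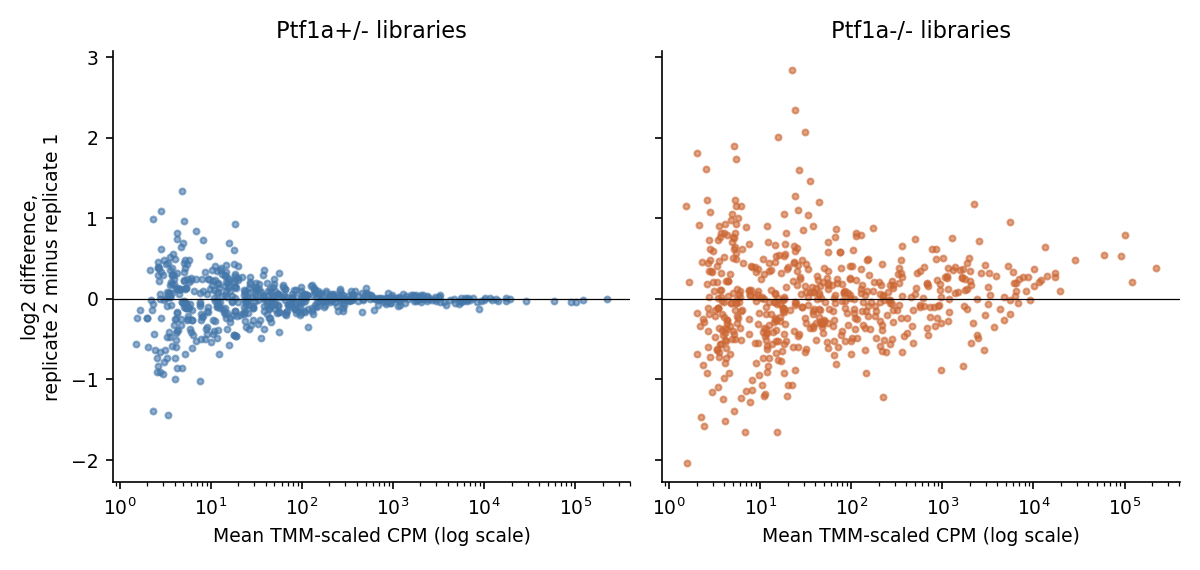
Difference in log2 TMM-scaled CPM between replicate 2 and replicate 1 of each genotype (vertical axis) against the mean TMM-scaled CPM over all 4 libraries (horizontal, log scale); each point is 1 of 584 miRNAs. The Ptf1a+/- differences close in on 0 as abundance rises, with a coefficient of variation of 1.39%. The Ptf1a-/- differences stay wide, with a coefficient of 22.6%.

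The comparison asked which miRNAs differ in the retina when Ptf1a function is lost; the series is about amacrine cell generation, miR-216b and the transcription factor gene Foxn3. In retinas without functional Ptf1a, 3 of 6 measured arms of the miR-216 and miR-217 cluster were lower, and 30 of 71 measured miRNAs of the imprinted Dlk1-Dio3 locus were higher. A few other miRNAs, among them miR-10a-5p, miR-190b and miR-200b-3p, were much lower, most of them with few counts. As lists, both sets passed a test with a preset correlation between miRNAs and neither passed with an estimated one (adjusted p = 0.696 and 0.295). Of 584 miRNAs with 10 or more counts in at least 2 libraries, 36 were higher and 21 lower in Ptf1a-/- at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). The 36 higher miRNAs had log2 fold changes from 0.46 to 2.53 with a median of 0.93, and the 21 lower ones from -5.08 to -0.52 with a median of -1.18. Both Ptf1a-/- libraries lay above both Ptf1a+/- libraries for 26.7% of the 584 miRNAs and below both for 31.5%. The Ptf1a+/- libraries lie so close together that this would often happen without an effect of genotype, so these shares measure no effect. The counts of 36 and 21 rest on taking the Ptf1a+/- libraries as replicates. With the pair summed into 1 library, an alternative added after seeing the data, only miR-190b-5p passed, while all 57 miRNAs kept their direction. That direction was kept says little, since these miRNAs were chosen by passing on the same counts. With library size as the only scaling, 4 were higher and 12 lower (25% of calls higher, against 63.2%), all miRNAs shifting by a median of -0.18. On the deposited CPM 1 was higher and 27 lower (3.57% of calls higher), with a median shift of -0.33.

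**Figure D2:**
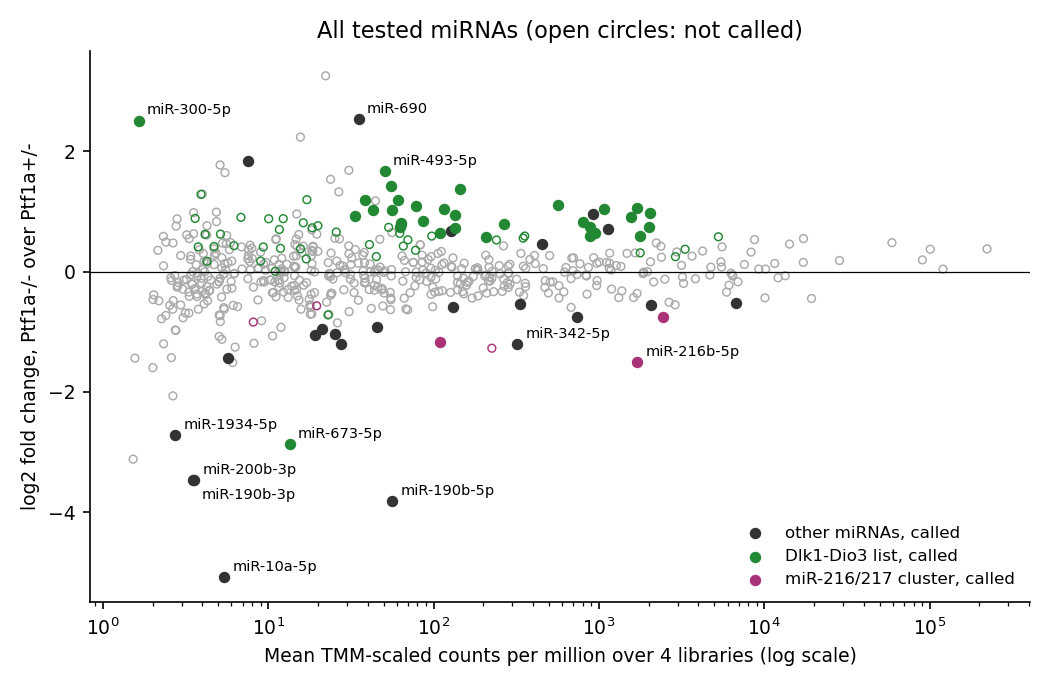
log2 fold change of each of the 584 tested miRNAs (vertical axis, Ptf1a-/- over Ptf1a+/-) against its mean TMM-scaled CPM over 4 libraries (horizontal, log scale). Filled points passed an adjusted p of 0.05 and open circles did not; the filled green points, members of the Dlk1-Dio3 list, lie above 0 except for miR-673-5p at -2.87.

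The miR-216 and miR-217 cluster, which includes the miRNA of the series title, lies on chromosome 11 (GRCm38; Mir216b 28746191 to 28746276, Mir216a 28757012 to 28757083 and Mir217 28763728 to 28763835, plus strand). Mir216a and Mir217 lie in an intron of the long noncoding RNA gene Gm12082. All 6 measured arms were below both Ptf1a+/- libraries in both Ptf1a-/- libraries, as were 31.5% of all 584 miRNAs. Of the 6, 3 fell at the threshold over all miRNAs (4 adjusted over the list alone). miR-216b-5p fell from 2516 ± 48.1 to 884 ± 351 CPM (TMM-scaled, mean ± SD, n = 2 each), a log2 fold change of -1.51 ± 0.26 (SE, adjusted p = 0.0244). miR-216a-3p fell from 151 ± 3.10 to 66.5 ± 12.2 CPM (log2 fold change -1.18 ± 0.16, adjusted p = 0.0124), and miR-217-5p from 3068 ± 34.9 to 1816 ± 423 CPM (-0.76 ± 0.17, adjusted p = 0.0499). The other arms did not pass: miR-216a-5p had a log2 fold change of -1.27 ± 0.35 (adjusted p = 0.0843), miR-217-3p of -0.84 ± 0.40 (0.258) and miR-216b-3p of -0.57 ± 0.37 (0.401). As a list the cluster had a median log2 fold change of -1.01 and an adjusted p of 0.00353 over 12 lists (limma's camera, preset correlation 0.01). The estimated correlation was 0.990, far above the preset, and with it camera gave a p of 0.282 (adjusted p = 0.696). The preset thus treats arms that moved together as nearly independent. The decrease was larger in Ptf1a-/- replicate 2 (median -1.44 against the Ptf1a+/- mean) than in replicate 1 (-0.67). With library size as the only scaling none of the 3 passed, though the median log2 fold change was -1.18 with all 6 arms below 0, and on the deposited CPM 3 arms were lower and the median was -1.32. These medians lay below that of all miRNAs by 1.00 and 0.988, against 1.01 with TMM. With the Ptf1a+/- pair summed none passed.

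**Figure D3:**
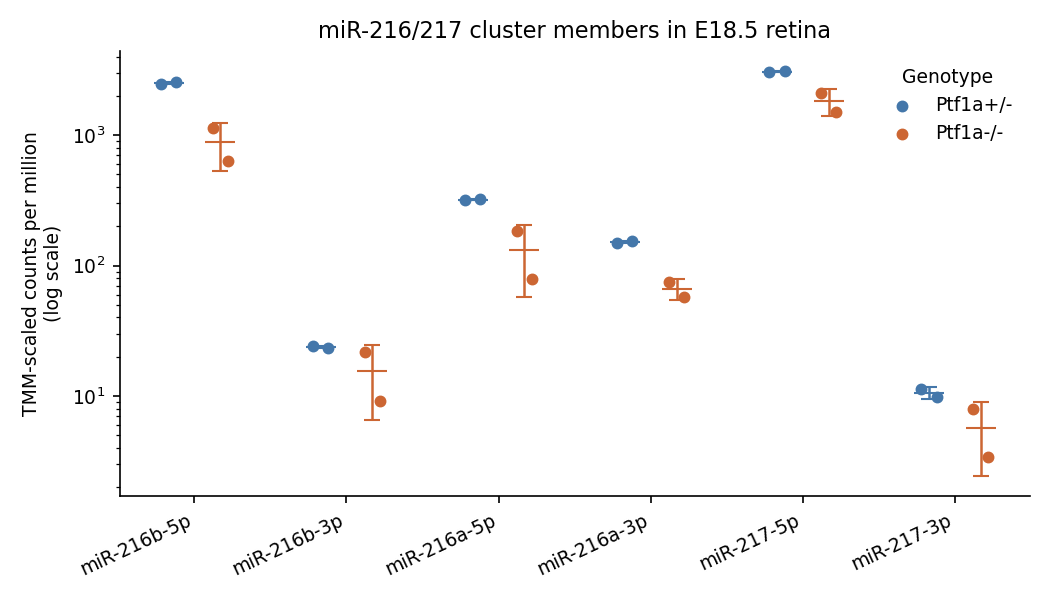
TMM-scaled CPM (log scale) of the 6 arms of the miR-216 and miR-217 cluster; points are the libraries, horizontal bars the mean and vertical bars 1 SD (n = 2 per genotype). Each Ptf1a-/- point lies below both Ptf1a+/- points of its arm, and for miR-216b-5p the means are 2516 and 884 CPM.

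The Dlk1-Dio3 locus carries a large cluster of imprinted miRNAs, expressed from the maternal chromosome in embryo and nervous system. Of its 71 measured members, 30 were higher in Ptf1a-/-, 1, miR-673-5p, was lower and 40 did not pass (42 higher and 2 lower adjusted over the list alone). In both Ptf1a-/- libraries 61 of 71 (85.9%) lay above both Ptf1a+/- libraries, against 26.7% of all 584 miRNAs. The higher members made up 30 of the 36 higher miRNAs. The 71 miRNAs come from 44 precursors on chromosome 12 from 109563692 to 109743795, all on the plus strand. Some lie in the noncoding RNA genes Rian and Mirg and some antisense to an exon of Rtl1. miR-300-3p rose from 1108 ± 18.4 to 2315 ± 97.0 CPM (log2 fold change 1.06 ± 0.11, adjusted p = 0.00937), miR-323-3p from 356 ± 0.421 to 769 ± 37.0 CPM (1.11 ± 0.11, adjusted p = 0.00937) and miR-493-5p from 24.3 ± 1.5 to 77.1 ± 9.68 CPM (1.67 ± 0.18, adjusted p = 0.00937). Further large increases were those of miR-379-3p (1.43), miR-369-3p (1.38), miR-299a-3p (1.18), miR-380-5p (1.18) and miR-127-5p (1.10). The largest fitted increase of the locus, 2.51 for miR-300-5p, rests on 4 counts in the Ptf1a+/- libraries together and 20 in the Ptf1a-/- libraries, a ratio of 6.02 with a 95% counting interval of 2.02 to 24.2. The list's median log2 fold change was 0.73, with an adjusted p of 1.61e-23 (camera, preset correlation of 0.01). The estimated correlation was 0.0608, above the preset, and with it camera gave a p of 0.0246 (adjusted p = 0.295). Its median over the Ptf1a+/- mean was 0.78 in Ptf1a-/- replicate 1 and 0.56 in replicate 2. With library size as the only scaling 4 members passed, and on the deposited CPM or with the Ptf1a+/- pair summed none did, while the median stayed above that of all miRNAs by 0.73 and 0.63 in the first 2 of these.

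miR-673-5p, from chromosome 12 (109571990 to 109572080), went against its neighbours: it fell from 23.8 ± 1.44 to 3.17 ± 1.00 CPM (log2 fold change -2.87 ± 0.30, adjusted p = 0.00937). Its most frequent sequence carried T11C in both Ptf1a-/- libraries and in neither Ptf1a+/- library, with positions counted from 1 at the 5′ end of the miRNA. All sequences of miR-673-5p together had only 15 and 8 counts in the Ptf1a-/- libraries, against 96 and 107 in Ptf1a+/-. The Ptf1a+/- libraries had CTCACAGCTCTGGTCCTTGG, in replicate 1 with a further 3′ A, and the Ptf1a-/- libraries CTCACAGCTCCGGTCCTTGG, in replicate 2 with that A. Its partner arm miR-673-3p, chosen after its value was seen, had a log2 fold change of -0.72 ± 0.21 (adjusted p = 0.0991). On either side of the list's interval, miR-342-5p (in an intron of Evl, 108658620 to 108658718) fell from 449 ± 0.562 to 194 ± 29.3 CPM (-1.21 ± 0.14, adjusted p = 0.010), and miR-1247-3p (in an exon of Dio3os, 110278048 to 110278129, minus strand) from 38.3 ± 6.07 to 16.6 ± 2.26 CPM (-1.21 ± 0.23, adjusted p = 0.0293). Of their neighbours and partner arms outside the interval, chosen after their values were seen, miR-1247-5p fell too (-0.93 ± 0.18, adjusted p = 0.0293). The others did not pass, with log2 fold changes of -0.26 for miR-342-3p and 0.30, 0.88 and 0.30 for miR-345-5p, miR-3072-5p and miR-203-3p (adjusted p from 0.244 to 0.528). Of these, miR-3072-5p lies in an exon of Mirg, which also holds list members. miR-1188-5p, named after its value was seen, lies inside the interval but is not in the list (0.98 ± 0.38, adjusted p = 0.183). The ends of the interval are thus set by the list.

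**Figure D4:**
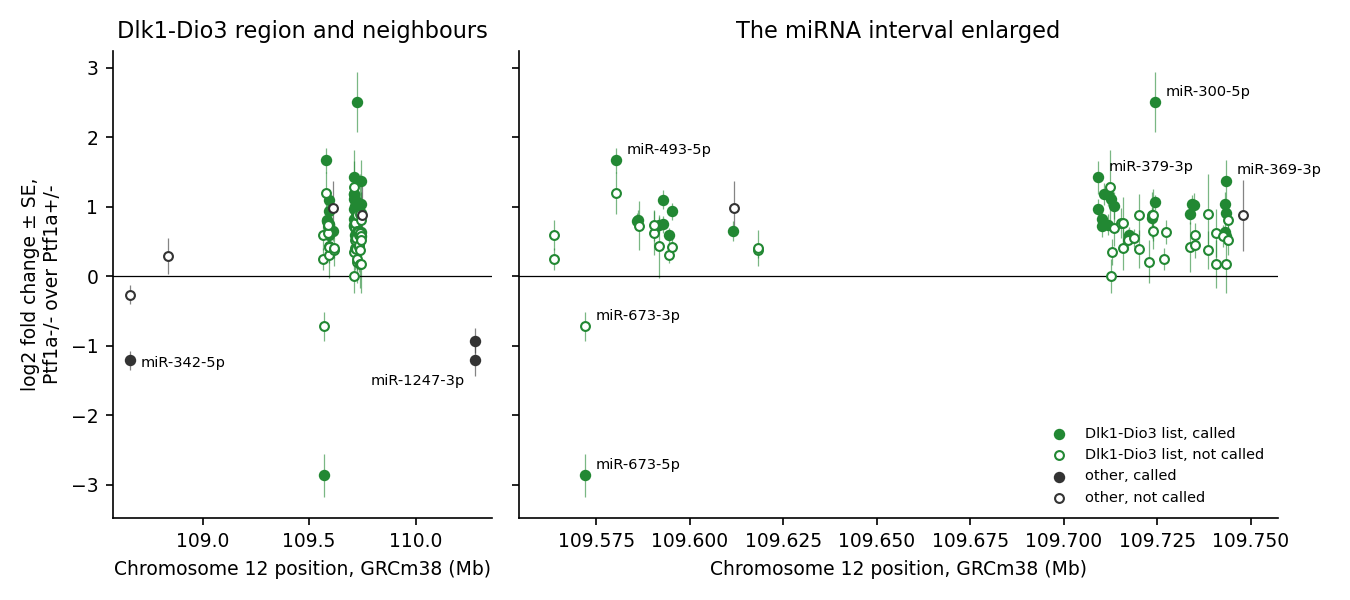
log2 fold change ± SE (vertical axis, Ptf1a-/- over Ptf1a+/-) of the miRNAs of the Dlk1-Dio3 region with a single matched precursor, against position on chromosome 12 in GRCm38 (Mb); the right panel enlarges the interval of the list. Of the 71 list members (green), 69 lie above 0 (67 with library size as the only scaling, 60 on the deposited CPM), the exceptions being both arms of miR-673. Of the miRNAs not in the list (black), miR-342-5p and miR-1247-3p lie at -1.21 and miR-345-5p at 0.30.

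The largest decreases were outside the cluster, most of them in miRNAs with few counts. miR-190b-5p (chromosome 3, 90070020 to 90070099, inside no other annotated gene) fell from 105 ± 8.26 to 7.41 ± 0.468 CPM (log2 fold change -3.81 ± 0.20, adjusted p = 0.000841), and its partner arm miR-190b-3p fell too (-3.47 ± 0.45, adjusted p = 0.0117). miR-10a-5p, encoded among the Hoxb genes (chromosome 11, 96317165 to 96317274), had 37 and 54 counts in the Ptf1a+/- libraries and 0 and 2 in the Ptf1a-/- libraries, a ratio of 0.0265 with a 95% counting interval of 0.00316 to 0.0983 (adjusted p = 0.010). miR-200b-3p, an epithelial miRNA (chromosome 4, 156055681 to 156055750, minus strand, in an intron of Ttll10), had 25 and 31 counts against 1 and 3 (log2 fold change -3.47 ± 0.49, adjusted p = 0.0124). Both arms of miR-1934 (chromosome 11, 69663043 to 69663125) were lower, the 5p arm by a log2 fold change of -2.71 ± 0.41 (adjusted p = 0.0156) and the 3p arm of -1.44 ± 0.31 (adjusted p = 0.0430). How the counting treated reads shared with the near-identical miR-10b or miR-190a is not given in the sources used here. Among the higher miRNAs outside the Dlk1-Dio3 list, miR-690 had the largest change (log2 fold change 2.53 ± 0.56, adjusted p = 0.0436) and miR-6240 the next (1.83 ± 0.38, adjusted p = 0.0387). The sequence of the former matched 16 annotated precursors and that of the latter none. The size of the miR-690 change leaned on Ptf1a-/- replicate 2, with 12.1 and 8.51 CPM in the Ptf1a+/- libraries and 31.8 and 88.4 in Ptf1a-/- replicates 1 and 2.

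None of the 5 lists for other retinal programmes passed with camera or with limma's directional fry test, which tests the members without the other miRNAs. With fry's mixed test, which takes changes both ways and was added after seeing the data, the miR-17/92 list passed (adjusted p = 0.0122) and the other 4 did not (0.0541 to 0.0805). None of the 6 measured arms of the miR-183, miR-96 and miR-182 cluster, the sensory cell and photoreceptor cluster, passed (median log2 fold change 0.32, camera adjusted p = 0.329; fry adjusted p = 0.0582). miR-183-5p stood at 49427 ± 581 and 69004 ± 18411 CPM (0.48 ± 0.21, adjusted p = 0.221), miR-96-3p at 0.54 and miR-96-5p at -0.34, with adjusted p of 0.134 and 0.210. Of 13 neuron-enriched miRNAs, miR-132-3p fell (28.0 ± 2.84 to 14.3 ± 1.01 CPM, log2 fold change -0.96 ± 0.22, adjusted p = 0.0471) and 12 did not pass, among them miR-218-5p (-0.55 ± 0.21, adjusted p = 0.173) and miR-132-5p (-0.59 ± 0.28, 0.259). The list's median was -0.24 (camera adjusted p = 0.329), and no member passed adjusted over the list alone. Of 25 miRNAs tied to retinal progenitor timing (let-7, miR-125 and miR-9), miR-125a-5p fell from 7898 ± 43.5 to 5522 ± 136.4 CPM (-0.52 ± 0.11, adjusted p = 0.0430) and 24 did not pass, including let-7f-5p (0.55 ± 0.14, adjusted p = 0.0756) and let-7c-2-3p (0.45 ± 0.14, 0.108), whose counts equal those of let-7a-1-3p, named after its values were seen, in every library, so that both shared their reads. Their median was 0.14 (camera adjusted p = 0.362; 0 adjusted over the list alone). None of the 20 members of the miR-17/92 paralog clusters, which accompany proliferation, passed. Their median was 0.01, their mean -0.09 and the camera direction down (adjusted p = 0.480). miR-18a-3p stood at -0.61 ± 0.16 (adjusted p = 0.0779), miR-93-3p at -0.63 ± 0.17 (0.0811) and miR-20a-5p at 0.42 ± 0.16 (0.183). Of 10 members of the miR-181 family, reported in the inner retina, miR-181b-1-3p fell (34.3 ± 0.406 to 16.7 ± 2.88 CPM, -1.04 ± 0.21, adjusted p = 0.0367), and 3 passed adjusted over the list alone. Of the 10, 8 lay below both Ptf1a+/- libraries in both Ptf1a-/- libraries (median -0.20, camera adjusted p = 0.117), as did 31.5% of all 584 miRNAs. miR-181a-5p and miR-181b-5p stood at -0.45 ± 0.12 and -0.44 ± 0.12, both with an adjusted p of 0.0843. On the deposited CPM, where all miRNAs shifted by a median of -0.33, the medians of the miR-183, timing and miR-17/92 lists were -0.06, -0.21 and -0.35.

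Markers of cell types that a dissected retina could also hold were measured in the same libraries. Of 3 pigment epithelium miRNAs, miR-204-3p fell from 394 ± 3.58 to 271 ± 26.3 CPM (log2 fold change -0.54 ± 0.12, adjusted p = 0.0436), while the far more abundant miR-204-5p stood at 3304 ± 30.1 and 3105 ± 228 CPM (adjusted p = 0.686) and miR-211-5p at -0.35 ± 0.29 (0.509). Of 3 lens and surface epithelium miRNAs miR-200b-3p fell, as given above, and miR-203-3p (0.30 ± 0.14, adjusted p = 0.244) and miR-184-3p (-0.44 ± 0.28, 0.388) did not pass. Of 3 vascular and mural miRNAs none passed over all miRNAs and 1, miR-143-3p, did adjusted over the list alone (-1.03 ± 0.25, adjusted p = 0.0637 over all miRNAs), miR-126a-3p standing at -0.35 ± 0.24 (0.416) and miR-126a-5p at 0.31 ± 0.28 (0.530). No blood cell miRNA passed of 3 measured. miR-486a-5p and miR-486b-5p, which shared their reads, stood at 0.15 ± 0.22 (0.737) and miR-486a-3p at -0.03 ± 0.23 (0.961). No striated muscle miRNA passed of 4 measured, with miR-1a-3p at 0.55 ± 0.24 (0.219), miR-133a-3p at 0.44 ± 0.48 (0.622) and miR-206-3p at 0.31 ± 0.42 (0.720). The camera adjusted p of the 5 marker lists lay between 0.329 and 0.729. With 3 or 4 measured members each, these tests cannot exclude that the libraries differed in the other tissue they held. Whether such a difference contributed to the lower levels of miR-200b-3p, miR-143-3p or miR-10a-5p was not tested.

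None of the 10 most abundant miRNAs passed. miR-9-5p, a neural progenitor miRNA and the most abundant, stood at 193655 ± 99.1 CPM in Ptf1a+/- and 251707 ± 46813 CPM in Ptf1a-/- (log2 fold change 0.38 ± 0.20, adjusted p = 0.300). miR-26a-5p stood at 118854 ± 874 and 122284 ± 12932 CPM, and miR-182-5p at 87990 ± 1714 and 113886 ± 43243 CPM (adjusted p = 0.908 and 0.454). let-7i-5p, miR-30d-5p, miR-99b-5p and let-7g-5p had log2 fold changes of 0.19, 0.18, 0.15 and 0.46, with adjusted p from 0.111 to 0.622.

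The most frequent sequence of a miRNA, which shows where its ends were cut and any base that differs from the reference, was equal in all 4 libraries for 408 of 584 miRNAs (69.9%). For 11 miRNAs both libraries of each genotype shared a sequence that neither library of the other had, 5 of them among the 325 miRNAs with 100 or more counts in at least 2 libraries. These 5, named after they were seen, were miR-204-5p, miR-467a-5p, miR-690, miR-1843b-5p and miR-6239. An internal base difference was the most frequent sequence in at least 1 library for 19 miRNAs, and for 1 of these, miR-673-5p, it separated the genotypes.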

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

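All tests weighed in this part were chosen after the results they bear on had been seen.

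The total behind the deposited CPM exceeded the listed counts by a larger share of it in both Ptf1a-/- libraries, 22.7% in replicate 1 and 27.9% in replicate 2, than in the Ptf1a+/- libraries (17.05 and 16.3%). What this excess counts is not given in the sources used here. In the calculations this excess enters only the comparisons on the deposited CPM, through its total. Whether reads of the same kind also lie among the listed miRNAs was not tested.

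The higher levels of Dlk1-Dio3 miRNAs are the broadest pattern in the comparison, though only 30 of 71 members passed as higher. Of the others, 40 did not pass and 1, miR-673-5p, was lower. The list did not pass camera with an estimated correlation (adjusted p = 0.295). Scaling between libraries was checked only by the list's median log2 fold change. It stayed above 0 under 5 scalings, the lowest being 0.297 on the deposited CPM. A scaling moves all miRNAs of a library by about the same amount, and the check was set after these medians were known, so it decides little. GC content and length are argued against as the cause. Other miRNAs of equal length and a GC content within 5 percentage points were found for 67 of the 71 members. Their median log2 fold change was -0.106 (95% bootstrap interval -0.148 to -0.00464) against 0.73 for the list. A single unusual Ptf1a-/- library is also argued against, the lower of the medians of the Ptf1a-/- libraries being 0.562. Both medians are taken against the same Ptf1a+/- mean, so an unusual Ptf1a+/- pair, which may be 1 RNA sample, stays open. A different haplotype at this imprinted locus in the Ptf1a-/- embryos cannot be told apart from an effect of Ptf1a: 1 list member, miR-673-5p, carried a base difference in both Ptf1a-/- libraries only, which neither shows nor excludes a different haplotype over the whole locus. A response to the loss of Ptf1a or of the cell types that need it stays open and untested, as does a difference in litter or stage.

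For miR-673-5p, a sequence variant between the mice is a candidate explanation: 2 libraries, both Ptf1a-/-, had T11C in its most frequent sequence, and reads with a mismatch may be counted less often. These 2 libraries held only 15 and 8 counts of miR-673-5p, so the base difference rests on few reads. Less precursor alone is argued against, since the log2 fold change of the 5p arm was 2.15 below that of the 3p arm (-2.15 ± 0.37, SE). An effect of the base on processing of the hairpin, and a decrease of the precursor as a part of the change, stay open.

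For the near identity of the Ptf1a+/- libraries, 1 RNA sample prepared or sequenced as both cannot be told apart from pooled RNA or from separate animals that differ little. Their chi-square per degree of freedom of 1.11 for miRNAs with 20 to 2000 counts is the near identity itself and decides nothing, and over all miRNAs with 20 or more counts it was 1.85 (p = 5.30e-32), beyond sampling noise. With the pair summed into 1 library only 1 of the 57 miRNAs passed.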

How the results depend on the processing

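All 57 called miRNAs kept their direction under each of the 17 alternatives in which they were tested (49 of them with 100 counts in 2 libraries). They were chosen by passing on these same counts, so this was largely fixed beforehand and adds little support. How many passed depended on which libraries set the spread. Summing the Ptf1a+/- libraries was chosen after seeing the data. The counts below are of miRNAs higher, lower, members of the miR-216 and miR-217 cluster lower and Dlk1-Dio3 members higher, against 36, 21, 3 and 30 in the report (6.16% higher and 3.60% lower of 584). They were 4, 12, 0 and 4 with library size only (0.685 and 2.05%), and 12, 9, 1 and 11 with no count filter (0.956 and 0.717% of 1255). With the Ptf1a+/- libraries summed as 1 they were 0, 1, 0 and 0 (0.171% lower), edgeR finding 62 at an unadjusted p under 0.05. On log2(CPM + 1) or log2(CPM + 0.5) of the deposited CPM, limma-trend called 1, 27, 3 and 0 (0.171% higher), and without a filter 0, 0, 0 and 0, with 199 of 1265 at an unadjusted p under 0.05. Leaving out each library in turn gave 0 to 24.3% higher, 0.171 to 22.6% lower, 0 to 6 cluster members and 0 to 58 Dlk1-Dio3 members. Without Ptf1a+/- replicate 1 there were 0 higher and 5 lower, and without Ptf1a+/- replicate 2 there were 0 and 1 (60 and 56 at an unadjusted p under 0.05, edgeR). Without Ptf1a-/- replicate 1 the shares were 24.0 and 21.1%, and without Ptf1a-/- replicate 2 they were 24.3 and 22.6%. Leaving out a library of one genotype leaves the spread to the other pair, which for Ptf1a+/- is small, and the lone library is assumed to vary like them. The remaining settings gave 25 to 42 higher, 15 to 21 lower and 2 to 4 cluster members, DESeq2 calling 42 and 17. The replicate numbers name nothing shared, and deviations of same-numbered libraries correlated at 0.0503 across miRNAs. With the number as a block the counts were 5, 7, 0 and 4 (0.856 and 1.2%). Why the other settings moved the counts was not tested.

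With an estimated correlation, the adjusted p of the list tests rose from 0.00353 to 0.696 (miR-216 and miR-217) and from 1.61e-23 to 0.295 (Dlk1-Dio3). With the Ptf1a+/- libraries also summed it rose to 0.785 for both. With the preset correlation both stayed under 0.05 in each other setting run. Leaving out each library gave adjusted p of 0.414 to 0.899 for the miR-17/92 list and 0.128 to 0.759 for blood cell markers, both changing direction without Ptf1a-/- replicate 2. Most frequent sequences were equal in 250 of 285 miRNAs with 100 counts in all 4 libraries. This is a larger share (87.7%, against 69.9% in the report) of fewer miRNAs, and the cause of the larger share was not tested. They were genotype-specific for 5 (100 counts in 2 libraries) and 3 (in all 4), against 11.

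Of 62 named miRNAs, 27 were called and none of these changed direction, which their selection on these counts makes likely. Of 1039 values under the alternatives, 727 kept direction and side of the threshold, 198 lost the threshold, 65 gained it and 49 changed sign. With library size only the log2 fold change became -0.050 for miR-486a-5p and miR-486b-5p, -0.15 for miR-26a-5p, -0.014 for let-7i-5p, -0.021 for miR-30d-5p and -0.043 for miR-99b-5p. On the deposited CPM with a pseudocount of 1, filtered or not, it became -0.044 for miR-203-3p, -0.22 for miR-486a-5p and miR-486b-5p, -0.028 for miR-126a-5p, -0.034 for miR-133a-3p and -0.13 for miR-206-3p. It became -0.31 for miR-26a-5p, -0.027 for miR-182-5p, -0.17 for let-7i-5p, -0.18 for miR-30d-5p and -0.20 for miR-99b-5p. With a pseudocount of 0.5 the values differed for miR-203-3p (-0.045), miR-126a-5p (-0.029), miR-133a-3p (-0.053) and miR-206-3p (-0.14). Leaving out each library gave ranges that cross 0 for miR-486a-5p and miR-486b-5p (-0.14 to 0.43), miR-486a-3p (-0.25 to 0.19), miR-133a-3p (-0.43 to 0.94) and miR-206-3p (-0.43 to 0.85). They also did for miR-26a-5p (-0.052 to 0.15), miR-182-5p (-0.059 to 0.72), let-7i-5p (-0.076 to 0.44) and miR-30d-5p (-0.055 to 0.40). The lower values came without Ptf1a-/- replicate 2, except for miR-133a-3p (without Ptf1a-/- replicate 1). Depth limits miR-10a-5p, miR-190b-3p, miR-200b-3p, miR-1934-5p and miR-300-5p, with 2 to 5 counts in 1 genotype together.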

Other observations

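The miRNAs named in this part, except miR-690, were chosen after their values were seen. Outside the fixed lists, 6 miRNAs were higher and 12 lower. Those named next were picked from the called ones, so lying on the same side in both Ptf1a-/- libraries adds little support. miR-6540-5p, from an intron of Gap43, a gene of growing axons (chromosome 16, 42303362 to 42303469, minus strand), rose from 628 ± 2.80 to 1216 ± 41.4 CPM (TMM-scaled, mean ± SD, n = 2 each; log2 fold change 0.95 ± 0.10, edgeR adjusted p = 0.00937). miR-7b-5p, of a family abundant in neuroendocrine cells, rose from 859 ± 34.7 to 1408 ± 197 CPM (0.71 ± 0.13, adjusted p = 0.0293), and miR-1224-5p, from an intron of Vwa5b2, from 99.1 ± 7.45 to 157 ± 5.49 CPM (0.67 ± 0.13, adjusted p = 0.0293). Among the lower ones, miR-328-3p fell from 930 ± 2.76 to 550 ± 27.3 CPM (-0.76 ± 0.11, adjusted p = 0.0124), miR-296-3p from 2452 ± 3.49 to 1673 ± 143.5 CPM (-0.55 ± 0.11, adjusted p = 0.0387), miR-222-3p from 158 ± 3.8 to 105 ± 7.98 CPM (-0.59 ± 0.13, adjusted p = 0.0436) and miR-199a-5p, a mesenchymal miRNA, from 26.0 ± 2.73 to 12.6 ± 0.966 CPM (-1.05 ± 0.22, adjusted p = 0.0430). Each of these was on the same side in both Ptf1a-/- libraries, and none passed with the Ptf1a+/- libraries summed into 1.

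Both arms of a precursor tended to move together: over 152 precursors with both arms measured, their log2 fold changes correlated across precursors at r = 0.717, and at 0.661 with the Dlk1-Dio3 list left out (68.4 and 61.6% with the same sign). Precursors are not independent replicates, and no p is given.

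Some entries had more counts mainly in Ptf1a-/- replicate 2: miR-6236, which matched no annotated precursor, had 14 and 21 counts in the Ptf1a+/- libraries and 37 and 232 in Ptf1a-/- replicates 1 and 2, miR-1195, which also matched none, had 53 and 70 against 69 and 249, miR-6538, with a single precursor, 51 and 51 against 44 and 195, and miR-690, with 16 precursors, 47 and 40 against 123 and 287. Of these only miR-690 passed (adjusted p = 0.0436), and the library is the one whose deposited CPM total exceeded its listed counts by the largest share, 27.9%.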
